A study of Oryzias latipes with 3 samples.

How the data were processed

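Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole medaka (Oryzias latipes) embryos at developmental stage 24 for acetylation of lysine 27 and trimethylation of lysine 4 on histone H3. H3K27ac is found at active promoters and enhancers, and H3K4me3 mainly at promoters. The embryos had been raised at 26 °C, and chromatin of 600 embryos went into each sample, per the labels' protocols. Fragments of 200 to 300 bp were kept for sequencing, per the same protocols. The series holds 3 samples, of which 2 were precipitated with an antibody against H3K27ac and 1 with an antibody against H3K4me3. A peak list was used for 1 sample of each mark. The second H3K27ac sample was not analysed here.

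Reads were aligned with Bowtie, per the submitters' processing notes, with no version named there. The authors' peak names contain MACS, the name of a peak caller that tests read density against a local background. The version, its settings, any control library, the genome build and any pooling of samples are not given in the sources used here. Each deposited list holds the chromosome, start, end, name and score of every peak. The deposited score is the peak caller's own value per peak and was used only within its list, to rank, split, filter and describe peaks by their median; differences of median score have no unit and are not compared between lists. Its meaning is not stated; the smallest values were 50.0 for H3K27ac and 50.01 for H3K4me3. Scores pile up at exactly 3100, a value shared by 62 H3K27ac and 882 H3K4me3 peaks, so the strongest peaks were not well ranked among themselves. Peak names numbered every entry of each list without a gap. Read depth is unknown, because the lists carry no read counts. Intervals given below cover counting error or the spread between chromosomes, not the spread between embryos or libraries. With 1 list per mark there was no replicate check, and no p-value was computed, since peaks are not replicates.

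Peaks lay on 24 chromosomes. The gene table at hand is of assembly ASM223467v1, and on 8 of the 24 chromosomes peaks continued past its last gene. On chromosome 2 the last peak ended at 31.1 Mb and the last gene at 25.4 Mb. The coordinates are therefore of another build, and gene symbols, start sites and gene lists planned for this series were not used here. Positions are 1-based in the build of the lists.

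An overlap was counted when peaks of the 2 marks shared at least 1 bp, with bedtools 2.31.1 and an equivalent array routine that gave identical counts. H3K27ac peaks that shared no base with H3K4me3 are called H3K27ac-only. Observed values were set against 1000 random placements in which each peak kept its width and chromosome, did not overlap peaks of its own list, and lay between the first and last peak of either mark. For distances of H3K27ac-only peaks to H3K4me3, placed peaks that shared a base with H3K4me3 were left out, as the observed ones share none. Shares carry Wilson 95% intervals and numbers of peaks exact Poisson 95% intervals. Differences of medians carry the 95% interval from 1000 resamples of whole chromosomes. H3K27ac-only peaks with edges up to 10 kb apart were stitched into domains. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used. The routines were tested on simulated data with planted overlaps and domains, and 2 unrelated simulated lists of 24027 and 12884 peaks gave an overlap 0.959 times that of placements.

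The comparisons, the alternatives and the rule for the regions named were fixed before the data were examined, except where stated. Named regions are the 10 domains with most H3K27ac-only peaks, the 10 widest H3K4me3 peaks and the 10 H3K27ac-only peaks of highest score, given by position in place of the nearest gene. For the case without usable genes the rule covered only the domains and the widest H3K4me3 peaks. The H3K27ac-only peaks of highest score were therefore named by position outside it. Alternatives covered the overlap rule, the score threshold, fixed peak widths, the stitching gap and the placement scheme. Placements without stretches of over 500 kb that lack peaks, shifts of a whole list along the chromosomes, placements within 1 Mb windows, domains moved with their peaks kept off H3K4me3, and prior merging of peaks up to 2 kb apart were added after the data had been seen.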

Results

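The H3K27ac list held 24027 peaks (exact Poisson 95% interval 23724 to 24333), and the H3K4me3 list held 12884 (12662 to 13108). Both lists covered the 24 chromosomes. H3K27ac peaks had a median width of 1078 bp (interquartile range 769 to 1531) and together covered 30.4 Mb, or 4.26% of the 714 Mb between the first and last peaks of the chromosomes. H3K4me3 peaks had a median width of 1151 bp (interquartile range 883 to 1454) and covered 15.7 Mb, or 2.19%. The widest peaks measured 7462 bp for H3K27ac and 6599 bp for H3K4me3. Each mark was represented by a single list, so none of the values below has a replicate check.

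Both marks were unevenly distributed among chromosomes. H3K27ac density ran from 24.3 peaks per Mb on chromosome 18 to 41.7 on chromosome 6. H3K4me3 density was also lowest on chromosome 18, at 13.6 peaks per Mb, and reached 25.9 on chromosome 8. Chromosome 8 carried 1.53 H3K27ac peaks for each H3K4me3 peak, whereas chromosome 20 carried 2.21. On chromosome 8, 56.8% of H3K27ac peaks overlapped H3K4me3 (95% interval 53.7 to 59.8), against 39.9% on chromosome 20 (36.7 to 43.2). Nearly all overlaps were one-to-one, so this contrast largely restates the 2 ratios of peak numbers. The share of H3K4me3 peaks overlapping H3K27ac on these chromosomes was 86.6% (83.8 to 89.0) and 87.1% (83.5 to 90.1), intervals that overlap. Among the 24 chromosomes it ran from 80.1% on chromosome 2 (75.7 to 83.8) to 89.3% on chromosome 3 (86.4 to 91.6). These intervals do not overlap, but they belong to the extremes picked from 24 chromosomes, so they do not test a difference.

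**Figure D1:**
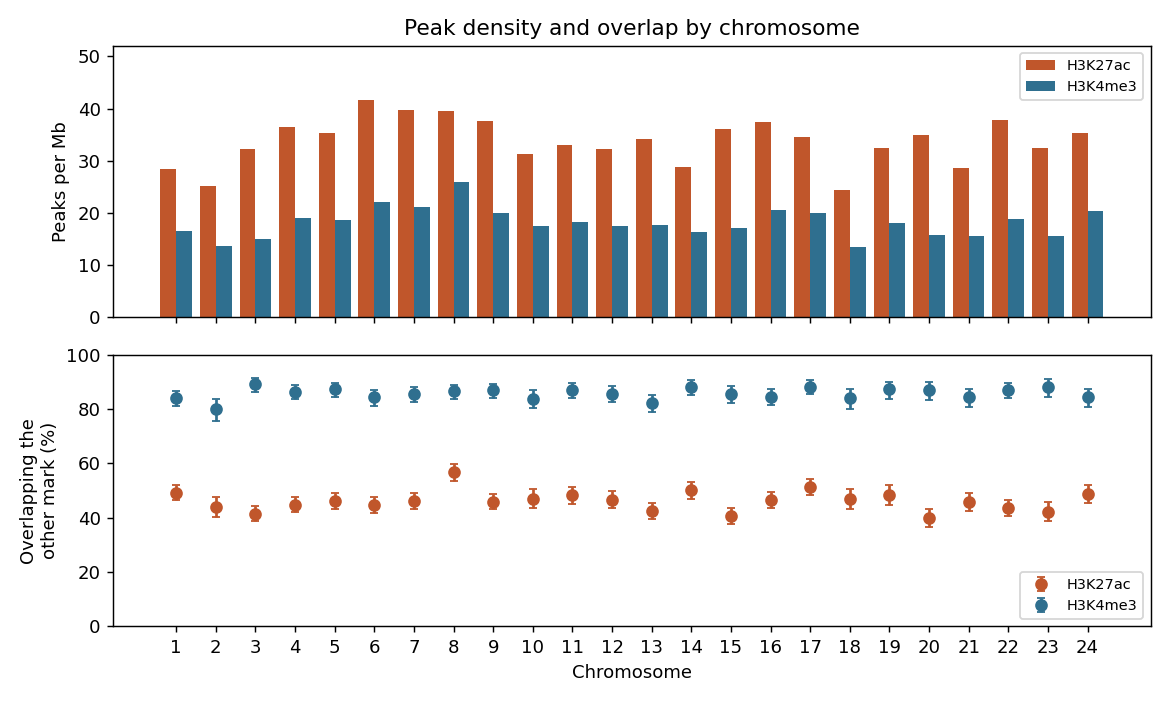
Peaks per Mb (upper panel, bars) and percent of peaks overlapping the other mark with Wilson 95% intervals (lower panel, points) on each of the 24 chromosomes, for H3K27ac and H3K4me3. H3K27ac density is lowest on chromosome 18 (24.3 per Mb) and highest on chromosome 6 (41.7 per Mb), and the overlap of H3K27ac peaks is highest on chromosome 8 (56.8%).

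The first comparison asked which acetylated regions of the embryo also carried the promoter mark. Of the H3K27ac peaks, 11089 overlapped an H3K4me3 peak, which is 46.2% of the list (95% interval 45.5 to 46.8), and the remaining 12938 did not. Of the shorter list of H3K4me3 peaks, 11065 overlapped H3K27ac, or 85.9% (85.3 to 86.5), and 1819 did not. Random placement of the H3K27ac peaks gave a mean overlap of 4.48% and never more than 4.87% in 1000 placements, so the observed share was 10.3-fold above placement. Placement of the H3K4me3 peaks gave 8.32% on average and at most 9.18%, again a 10.3-fold difference. The 2 folds must lie close, because nearly all overlaps were one-to-one and count in both lists. By bases, 75.5% of the H3K4me3-marked sequence was acetylated and 38.9% of the acetylated sequence carried H3K4me3. These base shares were 17.3-fold above placement. When the H3K27ac list was reduced by score to the length of the H3K4me3 list, 69.3% of its peaks overlapped H3K4me3 and 69.7% of H3K4me3 peaks overlapped H3K27ac, 2 shares that must lie close because nearly all overlaps were one-to-one.

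Where peaks of the 2 marks overlapped, their midpoints lay close together. Each sample came from whole embryos, so an overlap does not show both marks in the same cells. Among the 10786 pairs in which a peak of each mark overlapped a single peak of the other, the midpoints differed by a median of 91.0 bp, and in 75% of pairs by no more than 175 bp. The H3K4me3 peaks of these pairs were called wider, with a median of 1200 bp against 1098 bp for H3K27ac, and H3K27ac was wider in 35.2% of pairs. Read depth and the settings of the peak caller are unknown, so called widths do not compare the breadth of the marks themselves. H3K4me3 extended beyond H3K27ac at both ends in 37.7% of pairs, H3K27ac beyond H3K4me3 at both ends in 14.5%, and the marks were offset to opposite sides in 46.9%. Few peaks were split against the other mark: 110 H3K4me3 peaks overlapped 2 or more H3K27ac peaks, and 89 H3K27ac peaks overlapped 2 or more H3K4me3 peaks.

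Acetylated regions with H3K4me3 scored higher, but were hardly wider, than those without. The median score of H3K27ac peaks was 515 with H3K4me3 and 110 without, a difference of 405 (95% interval 391 to 423). Median widths were 1097 and 1052 bp, a difference of 45.5 bp (22.0 to 74.5) that shrank to 4.0 bp when classes were set by coverage of 50% of the peak. Ranked by score, 13.4% of the lowest quintile of H3K27ac peaks overlapped H3K4me3 (12.5 to 14.4), compared with 93.2% of the highest quintile (92.5 to 93.9). Ranked by width, the overlap was highest in the middle quintile, at 56.3% (54.9 to 57.7), and fell on both sides, to 35.0% (33.6 to 36.3) among the narrowest peaks and 41.3% (39.9 to 42.7) among the widest.

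**Figure D2:**
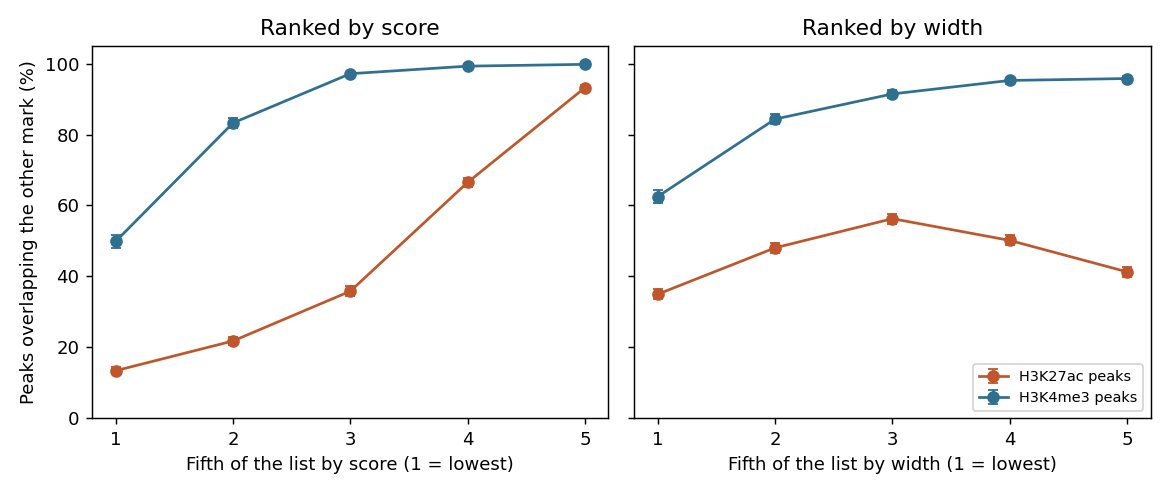
Percent of peaks overlapping the other mark, with Wilson 95% intervals, in quintiles of each list ranked by score (left) or width (right). Overlap of H3K27ac peaks rises with score from 13.4% to 93.2% but peaks at 56.3% in the middle quintile of width, while overlap of H3K4me3 peaks rises with both.

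The H3K4me3 peaks that lacked H3K27ac were narrow and of low score. Their median width was 788 bp against 1201 bp for those with H3K27ac, a difference of 413 bp (393 to 436). Their median score was 110 against 1289, a difference of 1179 (1128 to 1223). In the lowest quintile of H3K4me3 scores 49.9% of peaks overlapped H3K27ac (47.9 to 51.8), in the middle quintile 97.2% (96.5 to 97.7) and in the highest 99.8% (99.5 to 99.9). Of the 1819 peaks without H3K27ac, 94.7% were in the lowest 2 quintiles of score, and 23 were in the highest 2 quintiles.

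The 10 widest H3K4me3 peaks measured between 4395 and 6599 bp, and all 10 scored below the median of the list, 1014. This did not extend to broad peaks in general, as the 129 widest had a median score of 1663 and the rest of the widest quintile 1939. The widest lay at chromosome 12, 11457484 to 11464082. Another of the 10 lay 5.5 kb further along the same chromosome, at 11469587 to 11475337. H3K27ac covered 43.6% of the former and 51.4% of the latter. Acetylation covered 94.2% of a 6024 bp peak at chromosome 12, 13389211 to 13395234, and 96.7% of a 4395 bp peak at chromosome 18, 26760871 to 26765265. On chromosome 22, the peaks at 6715888 to 6722299 (6412 bp) and 18385825 to 18391194 (5370 bp) overlapped no H3K27ac peak.

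The second comparison concerned the acetylated regions away from H3K4me3. The 12938 H3K27ac-only peaks lay a median of 19.4 kb from the nearest H3K4me3 midpoint (95% interval 18.3 to 20.7, interquartile range 8.99 to 41.6 kb). Over 1000 random placements this median averaged 27.4 kb and was never below 26.1 kb. Placed peaks also reached sequence poor in H3K4me3, with 5.13% at 200 to 500 kb, against 1.45% observed. This placement value averages only a small first part of the 1000 placements. Placements within 1 Mb windows were not run for distances, so regional density shared by the marks was not set apart from closeness. Within 50 kb of an H3K4me3 peak were 80.2% of H3K27ac-only peaks, compared with 66.8% for placements and at most 68.1%. Within 10 kb the shares were 28.2% and 24.7%. Within 5 kb the order was opposite: 10.4% of H3K27ac-only peaks lay there, below the mean of 12.3% and below the lowest placement, 11.4%. The shortage lay between 2 and 5 kb. Within 1 kb there were 0.348% of H3K27ac-only peaks against a mean of 0.218%, a value that 3 of 1000 placements reached, and from 1 to 2 kb the share was 1.03 times that of placements also kept off the H3K27ac peaks at H3K4me3. The change was abrupt at 5 kb. The interval from 4 to 5 kb held 318 H3K27ac-only peaks and that from 5 to 6 kb held 456. The shortage followed the strength of the neighbour. Around H3K4me3 peaks in the highest tertile of overlapping H3K27ac score, the density per kb at 2 to 5 kb was 0.168 times that at 5 to 10 kb (0.122 to 0.218). The ratio was 0.863 (0.755 to 0.990) for the lowest tertile and 1.20 (1.04 to 1.38) for H3K4me3 peaks without H3K27ac.

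**Figure D3:**
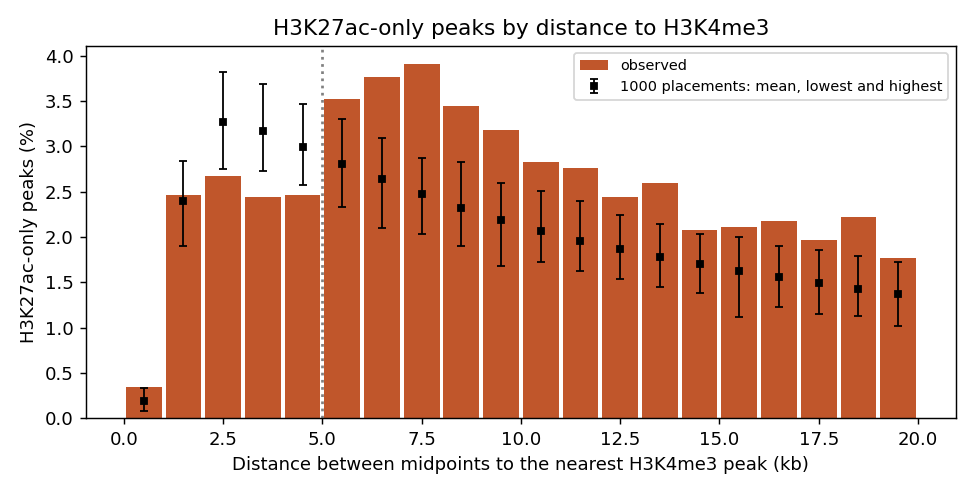
Percent of the 12938 H3K27ac-only peaks (bars) by distance in kb between their midpoint and that of the nearest H3K4me3 peak, in 1 kb intervals up to 20 kb, with the mean, lowest and highest of 1000 random placements (points and whiskers), here also kept off the H3K27ac peaks that overlap H3K4me3. Observed shares fall below the placements between 2 and 5 kb and above them in every interval from 5 kb (dotted line) to 20 kb.

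A small set of H3K27ac-only peaks scored high. The top quintile of H3K27ac scores contained 325 of them, with a median width of 2178 bp and a median distance of 13.3 kb to H3K4me3, compared with 1031 bp and 19.6 kb for the other H3K27ac-only peaks. The highest score, 2706, belonged to a 2024 bp peak at chromosome 4, 4699898 to 4701921, whose edge was 3.99 kb from the nearest H3K4me3 peak. Among the 10 highest, 9 had an H3K4me3 edge within 10 kb. The exception was a 2631 bp peak at chromosome 7, 14122776 to 14125406, at 27.5 kb. The second highest, at chromosome 13, 3894608 to 3895205, was 0.755 kb from H3K4me3. Chromosomes 9, 11 and 13 held 8 of the 10.

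H3K27ac-only peaks occurred in clusters. Stitching peaks up to 10 kb apart gave 8811 domains, of which 6283 were single peaks, 167 held 5 or more peaks and 6 held 10 or more. The 167 domains contained 1002 peaks, or 7.74% of H3K27ac-only peaks (7.30 to 8.22). Placements put 0.403% of peaks in such domains on average and 0.796% at most, while placements kept within 1 Mb windows gave 1.12% and at most 1.94%. The share depended strongly on the settings: it was 0.433% with a gap of 5 kb, 25.6% with 20 kb and 0.473% for the 50% of H3K27ac peaks with the highest score. Of the 167 domains, 86.2% (80.2 to 90.6) contained no H3K4me3 peak. The member peaks lack H3K4me3 by definition, so the domains were also moved at random with all their peaks kept off H3K4me3. A mean of 77.9% then contained none, and 2 of 1000 such placements reached the observed share, with 86.8% the highest. Only the H3K4me3 peaks themselves were avoided, not the sequence 2 to 5 kb from them, where H3K27ac-only peaks were scarce.

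The largest domain comprised 13 H3K27ac-only peaks over 90.1 kb at chromosome 15, 28703810 to 28793949, where no H3K4me3 peak was called and the nearest was 15.0 kb away. Another 3 domains held 12 peaks each. They lay at chromosome 9, 17571162 to 17649357, at chromosome 15, 27544260 to 27622056, and at chromosome 19, 9563472 to 9644936. Domains of 10 peaks were found at chromosome 4, 13589597 to 13638352, and chromosome 10, 23124479 to 23175662. The other 4 named domains held 9 peaks each, on chromosomes 3, 4, 6 and 10. Peaks took up between 24.6% and 38.3% of the sequence of the 10 domains. One of the 10 domains contained an H3K4me3 peak, that at chromosome 4, 32852306 to 32909732, which also had the highest median H3K27ac score of the 10, 363. The 6 domains of 10 or more peaks had median scores between 89.0 and 190. The median was 195 for all H3K27ac peaks and 110 for H3K27ac-only peaks. Of the other domains of 9 peaks, those on chromosomes 3 and 6 lay below 195 and that on chromosome 10, at 258, above it.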

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

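Of the 46 alternatives run, 24 were classed as having moved the value, 22 as having left it the same and 0 as having reversed it. The 22 include large changes: 10773 domains with a gap of 5 kb and 6516 with 20 kb, against 8811 as reported. For peaks in domains of 5 or more they include folds of 12.7 (gap 5 kb) and 200 (top 50%), against 19.2. Those folds count as the same only because single placements gave a wide range, 9.73 to 200. Shares, numbers of domains and distances have no direction, so only folds and differences could have reversed. The share of H3K27ac peaks overlapping H3K4me3, 46.2% as reported, was 44.2% when 50% of the peak had to be covered, 44.7% by midpoints, 48.1% with H3K4me3 extended by 1 kb, 50.7% for the top 50% of both lists by score and 69.3% with lists of equal length. The share of H3K4me3 peaks overlapping H3K27ac, 85.9%, became 83.9%, 84.6%, 87.9%, 94.4% and 69.7% under the same settings, and 85.2% both with 1 kb around each midpoint and for the top quartile of both lists. The remaining settings left the shares within their counting intervals, and other placement schemes left both folds between 9.76 and 10.5. Bases marked by both, as a share of bases marked by either, went from 34.6% to 37.5% in the top 50% of the lists. With classes set by 50% coverage, the width difference was 4.0 bp for H3K27ac and 359 bp for H3K4me3. The value of 4.0 bp was below the bootstrap standard deviation of the reported difference, 13.7 bp, so its direction is not established. The share of H3K27ac-only peaks in domains of 5 or more was 0.433% with a gap of 5 kb, 25.6% with 20 kb, 0.473% for the top 50% of H3K27ac peaks and 5.02% after merging peaks up to 2 kb apart. Its fold over placement, 19.2 as reported, was 6.64 with 20 kb and 6.90 with placement within 1 Mb windows, and reached 200 for the top 50%, where placements almost never gave such a domain. The share of domains without H3K4me3 was 1.46-fold above intervals placed at random and 1.11-fold above domains moved with their peaks kept off H3K4me3. The top 50% of peaks gave 2991 domains, since fewer peaks were stitched. Edge-to-edge distance from H3K27ac-only peaks to H3K4me3 had a median of 18.0 kb. All sequences were chromosomes, so leaving out scaffolds removed nothing. Start sites, annotation and gene lists were not run, as the gene table is of another build. No paired analysis was possible because each mark had 1 list, and read depth is unknown.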

Other observations

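Tests of the shortage at 2 to 5 kb and of calls lost beside a strong peak were chosen after the distances had been seen, and those with merged peaks and 1 Mb windows after the lists had been examined.

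Broad H3K4me3 peaks had more H3K27ac-only peaks around them than narrow ones, in counts not set against placements or regional density. Within 50 kb of the midpoint, the widest quintile of H3K4me3 peaks had a mean of 2.61 H3K27ac-only peaks and the narrowest quintile 1.82, a difference of 0.793 (95% interval 0.679 to 0.916 over resampled chromosomes). The 129 widest H3K4me3 peaks, from 2889 bp upwards, had a mean of 3.51. H3K4me3 peaks with and without H3K27ac had means of 2.11 and 2.01, a difference of 0.0978 whose interval, -0.0138 to 0.214, includes 0. Of all H3K4me3 peaks, 22.3% had no H3K27ac-only peak within 50 kb.

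Long stretches lacked peaks of both marks. There were 13 stretches of over 1 Mb without a peak, on 8 chromosomes, with a total of 25.5 Mb, while placements of both lists never left more than 0.358 Mb. The longest, 5.16 Mb, ran from 7643305 to 12803843 on chromosome 2, where the first peak of either mark lay at 4.37 Mb. Without these stretches chromosome 18 still had the lowest H3K27ac density, 27.4 peaks per Mb, but for H3K4me3 its 15.3 peaks per Mb lay above the 15.0 of chromosome 3. Sequence was not used here, so gaps in the assembly were not examined.

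H3K27ac-only peaks were scarce between 2 and 5 kb from H3K4me3, though not closer, and abundant just beyond. Space taken by the H3K27ac peaks on the H3K4me3 sites is argued against, since placements that kept off those peaks gave at least 11.1% within 5 kb, above the observed 10.4%. A candidate explanation is technical: a strong peak may raise the local background that the peak caller uses for its neighbours, so that weaker peaks beside it are not called; this needs the ChIP reads themselves to set that background, and whether a control library set it instead is not given in the sources used here. The ratio of densities at 2 to 5 kb and 5 to 10 kb differed by -0.695 (-0.817 to -0.589) between H3K4me3 peaks of the highest and the lowest tertile of H3K27ac score. Ranking within the H3K27ac list gave a similar trend but not a separate line of evidence. Of its highest quintile, 93.2% overlapped H3K4me3, against 13.4% of the lowest, so peak strength was not set apart from H3K4me3. Around the highest quintile of H3K27ac peaks by score the ratio was 0.286. Around the lowest it was 0.726, still below the placement mean of 0.990. Within the H3K4me3 list it was 0.920, 0.964 and 0.927 in quintiles 1 to 3, and fell only in quintiles 4 and 5, to 0.559 and 0.201. A real scarcity of acetylated regions next to active promoters stays open and untested.

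H3K27ac-only peaks clustered beyond placement. Splitting of a single acetylated region into peaks up to 2 kb apart is argued against as the full account. In the list with such peaks merged, 5.02% of peaks lay in domains of 5 or more and at most 0.697% in placements. Peaks more than 2 kb apart were not merged, so splitting of a region by longer gaps stays open. Regional density along the chromosomes would have to give such domains in placements within 1 Mb windows, but the highest of 1000 was 1.94%, against 7.74% observed. Density differences over less than 1 Mb, and the genes themselves, were not examined. Whether the shortage of H3K27ac-only peaks at 2 to 5 kb from H3K4me3 raised the share of domains without H3K4me3 stays open and untested.

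H3K4me3 peaks without H3K27ac were mostly weak calls, and 0.248% of the top quartile by score (0.126 to 0.489) lacked H3K27ac; since this follows from their low scores, calls near the threshold cannot be told apart from weak sites without acetylation. H3K27ac just outside the peak edges accounts for few, since 14.4% (12.9 to 16.1) had an H3K27ac edge within 1 kb. Loss of an H3K27ac call beside a strong H3K27ac peak stays open: among H3K4me3 peaks of the lowest 2 quintiles of score, 42.8% lacked H3K27ac at 2 to 5 kb from a top-quintile H3K27ac peak and 31.8% at 5 to 10 kb, a difference of 11.0 percentage points (1.88 to 19.5). Over 10 kb from a top-quintile peak, where 1445 of these weak peaks without H3K27ac lay, the share was 35.4%. Against that, the excess at 2 to 5 kb was 7.44 points (-0.419 to 14.4, which includes 0). Up to 2 kb the share without H3K27ac was 8.78%. So near a top-quintile peak, an H3K4me3 peak can overlap that same peak, so this share does not bear on lost calls. The design names no group that bears on a biological explanation, and none was tested.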
